A study of Mus musculus with 3647 samples.

How the data were processed

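The series holds single nuclei and Patch-seq samples of mouse brain, and each sample is 1 nucleus or cell. Per the labels' protocols, nuclei were isolated on a sucrose gradient, sorted by flow cytometry on a DNA dye alone, on the dye and GFP or on the dye and NeuN, and made into libraries with a modified Smart-seq2 protocol in plates of 96 wells. Samples were grouped by the labels for plate type, tissue and sort, never by their values, and each table column was matched to a sample by the name in its labels. Samples with expression values, out of all samples, were 753 of 768 TRN nuclei sorted with NeuN (8 plates), 694 of 1249 TRN nuclei sorted without it (13 plate names), 240 of 383 nuclei of adjacent tissue (4 plates), 440 of 624 hippocampal nuclei (7 plates), 168 of 192 from M2 cortex (3 plates), 149 of 192 from somatosensory cortex (2 plates), 71 of 96 from striatum (1 plate), 43 of 48 hippocampal nuclei without a sort label and 95 of 95 Patch-seq samples (3 batches). The other 994 samples had no column in the tables used here and entered no analysis. How the missing samples were selected is not given in the sources used here, so shares describe nuclei with values. Every nucleus with values had at least 1503 detected genes, while Patch-seq libraries, none of them missing, went down to 746. The nuclei with values thus look selected on detected genes. Every column was matched to a sample, no column of per-sample values was left over and no column repeated another.

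Per the submitters' processing notes, the tools were RSEM, Bowtie, TopHat2 2.0.10 and Seurat 2.2.0 and the genome build was mm10; the notes as used here give no role or order for them. The authors deposited TPM for the non-TRN nuclei (871 columns) and the Patch-seq samples (95 columns), with 23420 genes in each table and column totals between 999999.32 and 1000000.69. The TRN table (1687 columns, the same number of genes) was deposited by the authors as the natural log of 1 plus TPM times a factor of each nucleus, as the values themselves show. Undoing the logarithm and rescaling each column to the same total put all 236907 values under 2 TPM within 0.1 steps of a whole multiple of 0.01, the precision of the other tables, in all 1687 columns. The factors ran from 0.288 to 6.03 with a median of 0.777. The design fixed before the data were examined had assumed TPM in every table; the recovered TPM were used so that it could be kept, and the deposited scaling was added as an alternative. TPM corrects for gene length and library size within a library, so an abundant transcript lowers the values of all others. TPM keep no read counts, so depth and its precision are unknown, and the number of genes with TPM above 0 is given in its place. No UMI counts were used.

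The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9. The TRN and non-TRN tables were clustered separately. Genes found in at least 10 nuclei entered as log2 of TPM plus 1, the 2000 most variable were scaled and limited to 5 SD, and 30 principal components and 15 nearest neighbours fed Leiden clustering at resolution 1. The partition of highest modularity among 20 random starts was kept. That choice was made after seeing the data: a single start was tried first, on unrounded and then on rounded values, and its classes depended on the start. The criterion does not use class names. Over the 20 starts at resolution 1, TRN-table GABAergic neuron-like nuclei numbered 848 to 899, thalamic glutamatergic 211 to 231 and striatal projection neuron-like 0 to 23; in the non-TRN table GABAergic numbered 301 to 321, glutamatergic 102 to 253 and neuron-like nuclei without a transmitter call 44 to 228.

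Clusters were named from marker genes fixed before the data were examined, with thresholds set after the marker shares were seen. A marker counted when found in at least 50% of a cluster's nuclei. Neuron-like clusters needed 5 of 7 neuronal markers, GABAergic ones 3 of 4 GABAergic markers, and glutamatergic ones a vesicular glutamate transporter and 3 thalamic or cortical and hippocampal markers. Other classes needed 3 markers and, for glia, at least 50% of their list. No doublet caller was run: clusters with markers of neurons and of another cell type, or with too few markers, were left unnamed and out of the comparisons of expression.

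The comparisons were NeuN-selected against unselected neuron-like nuclei (714 against 286), adjacent against TRN GABAergic nuclei (65 against 815), TRN against GFP-sorted GABAergic nuclei (815 against 307), each GFP-sorted region against the others (88 nuclei in hippocampus, 94 in M2 cortex, 113 in somatosensory cortex and 12 in striatum), and Patch-seq samples against NeuN-selected GABAergic nuclei (95 against 584). The GFP-sorted mean is the mean of the 4 region means. The labels name no animal, so each group counts as 1 sample and no p-value or standard error was computed from nuclei. Shares have exact binomial 95% intervals, and plate ranges use plates with enough nuclei (20 for shares and correlations, 5 for plate means). Expression is compared as the log2 ratio of mean TPM with a pseudocount of 1 TPM. Lists of genes fixed before the data were examined are given by their median and its percentile among 10000 random lists of equal size, each member drawn from the 200 genes nearest in mean expression. Tables were deposited separately, so ratios across them also carry any difference between tables, plates and sorts.

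The rule for named genes was fixed before the data were examined. It takes the 12 highest and the 12 lowest log2 ratios among genes found in at least 30% of nuclei of the higher group whose mean on every plate of 1 group lies above that on every plate of the other, leaving out unnamed gene models, clone names and pseudogenes. Some genes are not reported here, although list medians and counts include them. Members of the fixed lists may also be named, and where their plates overlap they are given as values. For the axis, Spearman rho of each gene with log2 Spp1 minus log2 Ecel1 was computed within each plate with at least 20 GABAergic nuclei (13 plates, 707 nuclei) and averaged over plates, and genes found in at least 20% of nuclei with 1 sign on at least 80% of plates could be named. Genes carry the symbols of the tables, and coordinates and identifiers come from the GENCODE vM21 annotation of mm10, matched by symbol.

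The computation was tested on simulated data: in the adjacent comparison, simulated on 584 NeuN-selected nuclei and 6935 genes with 50 genes changed at each fold size, every plate lay apart for 100% of genes changed 8-fold or 0.125-fold, 88% of those changed 0.5-fold and 78% of those changed 2-fold, and for 3.24% of unchanged genes. The simulated nuclei were shuffled over plates of equal size, which removes differences between plates. The real comparison set 3 adjacent plates against 21 TRN plates of unequal size. These shares therefore check the code and do not give the recovery or error rate of the real comparison. The median error of the log2 ratio of 0.125-fold genes was 0.207 against the simulated fold, above the limit first set, and 0.0253 against the ratio expected with the pseudocount, which then became the target with the limit kept.

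Alternatives were clustering resolutions of 0.5 and 2, pseudocounts of 10 and 0.1 TPM, differences of mean log2 values, leaving out the 10% of nuclei with the fewest detected genes or each plate, partialling out detected genes, Pearson instead of Spearman correlation, other filters on low genes, NeuN plates alone and adding the hippocampal nuclei without a sort label. Added after seeing the data were the deposited scaling, leaving out the Pvalb-low cluster, the other clustering starts, and random pairs matched on the share of nuclei. A planned share of mitochondrially encoded RNA was not analysed here, because none of its genes was measured in the tables used.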

Results

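RNA was sequenced from single mouse nuclei sorted into plates with 96 wells, and from single neurons of the thalamic reticular nucleus (TRN) whose contents were drawn into a recording pipette (Patch-seq). The TRN is a thin shell of GABAergic neurons that inhibits the thalamus. The labels list 3647 samples, each 1 nucleus or cell, and 2653 of them had expression values. They were TRN nuclei sorted with an antibody against the neuronal protein NeuN, TRN nuclei sorted on a DNA dye alone, and 240 nuclei of the adjacent thalamus and globus pallidus. Nuclei sorted on GFP, described by the submitters as Pvalb-positive, came from hippocampus (440), striatum (71), M2 cortex and somatosensory cortex. A further 43 hippocampal nuclei carried no sort label, and 95 samples were Patch-seq libraries. Expression is given as TPM, transcripts scaled to a fixed total in each nucleus, recovered for the TRN table from deposited natural log values. TPM keep no read depth, so depth is unknown and detected genes stand in for it. The median number of detected genes was 4983 with NeuN selection, 2426 without it, 2469.5 in adjacent tissue, 4218 in hippocampus, 4137.5 in M2 cortex, 3973 in somatosensory cortex, 2889 in striatum and 6654 in Patch-seq. The labels name no animal, so each group counts as 1 sample: no test between groups is possible, and ranges over plates describe the spread between plates, whose source is unknown. Intervals on shares are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only.

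The first comparison asks which cell types each TRN sort contained. Cluster names carry "-like" because they were rebuilt here from marker genes. Neuron-like nuclei made up 94.8% of NeuN-selected nuclei (93 to 96.3%) and 41.2% of unselected nuclei (37.5 to 45%). Plates ranged from 90.4 to 97.9% with NeuN selection and from 10 of 50 nuclei to 61.4% without it, over the 12 unselected plates with at least 20 nuclei. The 4 unselected plates that share a name prefix reached at most 32.1%, and the others had at least 43.1%. All 8 NeuN plates share another prefix that no unselected plate has, so sort and set of plates cannot be separated. Only 55.6% of unselected samples had values, against 98% of NeuN-selected ones, and every nucleus with values had at least 1503 detected genes. In unselected tissue oligodendrocyte-like nuclei had a median of 1988 detected genes and neuron-like nuclei 4374.5. Missing nuclei may therefore differ in cell type from those counted. Oligodendrocyte-like nuclei, the myelinating glia, were 42.8% of unselected nuclei, 39.2% of adjacent nuclei and 0.797% of NeuN-selected nuclei. Astrocyte-like nuclei were 11.5% of unselected and 17.9% of adjacent nuclei. Clusters with both neuronal and glial markers, or too few markers, were left unnamed and held 3.72% of NeuN-selected and 0.576% of unselected nuclei.

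**Figure D1:**
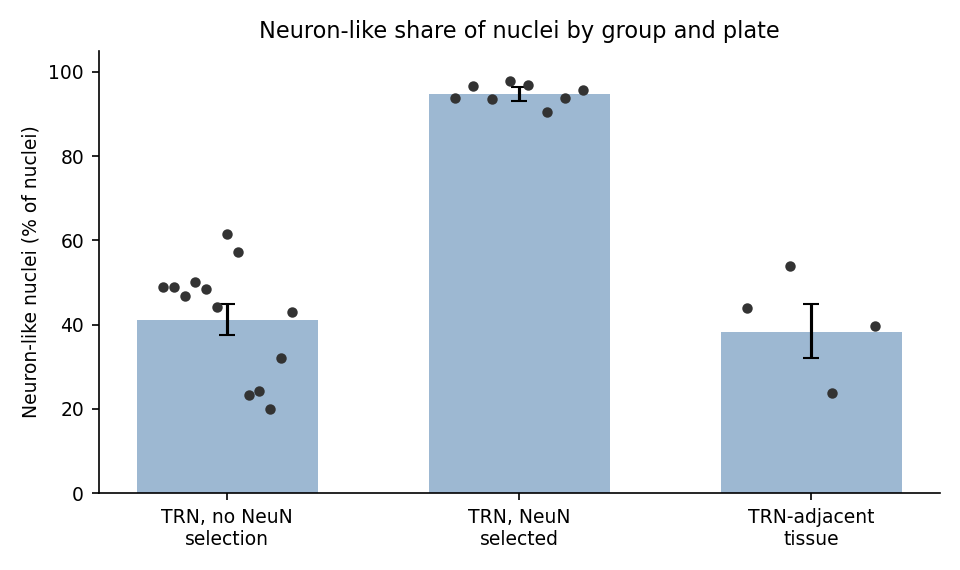
Neuron-like nuclei as a percentage of nuclei (vertical axis) in unselected TRN, NeuN-selected TRN and TRN-adjacent tissue; bars are shares over all nuclei with exact binomial 95% intervals and points are plates. The bars stand at 41.2%, 94.8% and 38.3%.

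Among neuron-like nuclei, glutamatergic nuclei with thalamic relay markers such as Slc17a6, a vesicular glutamate transporter, made up 18.5% of the TRN nuclei (16.1 to 21%, 1000 nuclei). The share was 18.2% with NeuN selection and 19.2% without it. In adjacent tissue, neuron-like nuclei were 38.3% of nuclei (92 of 240, 32.2 to 44.8%), and 29.3% of those were glutamatergic (27 of 92, 20.3 to 39.8%). The adjacent plate ThrP26 held 26 of these 27 nuclei, and without it the glutamatergic share was 1.54%. Thalamic glutamatergic nuclei on the adjacent plates thus came from 1 plate but for 1 nucleus, while the other 3 plates held GABAergic neurons and glia.

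Expression was also compared between NeuN-selected and unselected neuron-like nuclei. Necdin (Ndn, ENSMUSG00000033585.5), a paternally expressed gene of the Prader-Willi region, was the single gene that met the fixed naming rule, which asks for every plate of both sorts to lie apart and so does not show that other genes were alike; it did not meet the rule as a difference of mean log2 values, which was -1.80. Its mean was 544.5 TPM in NeuN-selected nuclei and 1145.7 TPM in unselected nuclei, a log2 ratio of -1.07, and every NeuN plate lay below every unselected plate. Oligodendrocyte markers had a median log2 ratio of 1.17 toward NeuN-selected nuclei, with 7 of 8 genes higher, and astrocyte markers 0.87, also with 7 of 8 higher; as differences of mean log2 values these medians were 0.37 and 0.06. The myelin gene Mog reached 2.43, but plates of the 2 sorts overlapped for it. These neuron-like nuclei had a median of 4972.5 detected genes with NeuN selection and 4374.5 without it.

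Adjacent tissue was compared with the TRN among GABAergic neuron-like nuclei, 65 of them adjacent, to ask which inhibitory neurons border the nucleus. The adjacent nuclei included striatal projection-type neurons. Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32 (ENSMUSG00000061718.12), averaged 729.1 TPM in adjacent and 12.6 TPM in TRN nuclei, a log2 ratio of 5.74, and was found in 35.4% and 2.82% of nuclei. The G protein regulator Rgs9 had a log2 ratio of 4.97, the adenosine receptor Adora2a 4.84, and the dopamine receptors Drd1a and Drd2 3.83 and 4.55. The transcription factors Bcl11b and Bcl11a, at 3.47 and 3.15, and the phosphodiesterases Pde10a and Pde2a, at 2.65 and 2.59, also had higher means in adjacent nuclei. Among genes with lower means were Copb2, a coat protein of Golgi vesicles, at -2.26, the membrane glycoprotein Cd200 at -2.11 and the lysosomal membrane gene Lamp2 at -1.47. The TRN genes Six3, a forebrain transcription factor, and Pvalb, a calcium buffer, hardly differed, at -0.10 and -0.08.

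With differences of mean log2 values 8 of the 24 genes named by the rule stayed named. These ratios describe which nuclei the adjacent plates held and not a shift across all their GABAergic nuclei. One of the 4 GABAergic clusters, the lowest in Pvalb, held 26 of the 65 adjacent nuclei, 6.49% of unselected TRN and 12.8% of NeuN-selected TRN GABAergic nuclei. At a finer clustering resolution of 2, 18 of those 26 adjacent nuclei were named striatal projection neuron-like. The median log2 ratio over the 6 striatal markers was 4.91; it was 1.14 at resolution 2 and -0.05 without that cluster, where Drd1a and Bcl11a turned to -1.37 and -1.07.

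TRN GABAergic nuclei were next set against GFP-sorted GABAergic nuclei of hippocampus, M2 cortex, somatosensory cortex and striatum, which asks how TRN neurons differ from Pvalb interneurons elsewhere. The tables were deposited separately and region values are averaged with equal weight, so the striatum's 12 nuclei count as much as the 88 or more of each other region. The fixed list of 28 forebrain patterning transcription factors went both ways, with 11 higher and 16 lower in the TRN and a median log2 ratio of -0.17. Of its members, Six3 (chromosome 17, 85613608 to 85629302, mm10) averaged 115.05 TPM in the TRN and 0.0394 TPM in the GFP-sorted nuclei, a log2 ratio of 6.80, and was found in 79.6% against 0.816% of nuclei. Isl1 and Meis2, homeobox factors of the same list, and the nuclear receptor Nr2f2, which is not on it, had log2 ratios of 5.62, 4.11 and 5.41. The peripheral myelin gene Pmp22 had the highest ratio, 8.25, followed by the purinergic receptor P2ry1 at 7.58. Other genes with higher means in the TRN were the endothelin-converting enzyme-like protease Ecel1 at 6.72, the thyrotropin-releasing hormone gene Trh at 6.46, the extracellular matrix gene Coch at 6.25 and the cholecystokinin receptor Cckar at 5.91.

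The genes that specify interneurons of the medial ganglionic eminence (MGE) were lower in the TRN. The median log2 ratio of the 7 listed genes was -4.08, with none higher in the TRN, and it was below every one of 10000 random lists matched on expression. Lhx6 (chromosome 2, 36081953 to 36105408, mm10), the LIM-homeobox factor that marks this lineage, averaged 0.0241 TPM in the TRN and 100.6 TPM in the other regions, a log2 ratio of -6.63. It was found in 0.736% of TRN GABAergic nuclei and 44.9% of the GFP-sorted ones. Sox6 and Satb1, which act downstream of Lhx6, had ratios of -4.72 and -4.85, the transcription factor Maf -3.78, and the neuregulin receptor Erbb4 -2.55. Nxph1, an extracellular ligand of neurexins, was the exception at -0.02. Other genes lower in the TRN included the laminin Lama3 at -5.88, Igfbp4 at -5.61 and the transcription factors Tcf4 and Nfib at -4.86 and -4.12. The list median depended on the scale: it was -2.22 with a pseudocount of 10 TPM and -2.44 as a difference of mean log2 values. On that last scale 11 of the 24 genes named by the rule in this comparison stayed named.

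**Figure D2:**
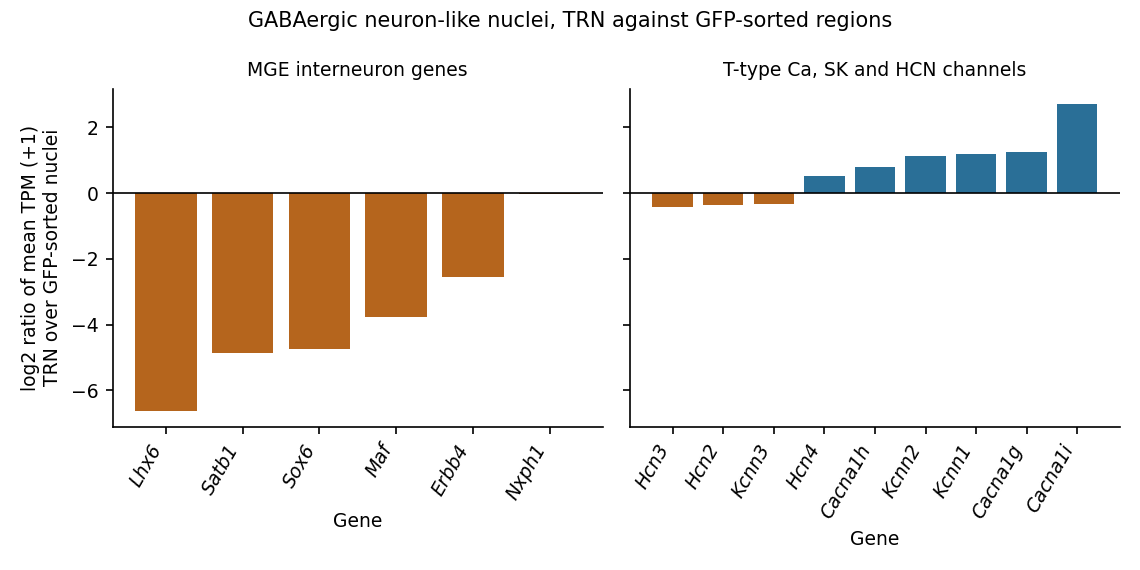
Log2 ratio of mean TPM plus 1 (vertical axis), TRN over GFP-sorted GABAergic neuron-like nuclei, with bars for genes of the MGE interneuron list and of the T-type calcium, SK and HCN channel list. Lhx6 stands at -6.63 and Cacna1i at 2.70.

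Channels linked to TRN bursting differed in both directions. The T-type calcium channel gene Cacna1i (chromosome 15, 80287238 to 80398279, mm10), which carries low-threshold current, averaged 51.3 TPM in the TRN and 7.03 TPM elsewhere, a log2 ratio of 2.70. Cacna1g, a second T-type gene, had 1.24, and the SK channel gene Kcnn2, which follows burst calcium, 1.13. Over the 10 T-type, SK and HCN genes the median was 0.65 with 6 genes higher, at the 99.3 percentile of random lists. The median had an SD of 0.653 over TRN plates, as large as itself, and ranged from 0.31 to 0.97 over the scalings and pseudocounts tried. The Kv1 and Kv3 channels of fast spiking had a median of -1.08 with 2 of 10 higher, which was -0.49 as a difference of mean log2 values, and Kcnc1 had -1.26. Of the metabotropic glutamate receptors 5 of 7 were higher, led by Grm3 at 2.95, while the AMPA receptor subunit Gria1 was lower at -3.71. Of the interneuron peptides, Sst had a higher mean in the TRN, at 2.67, and Tac1 a lower one, at -5.34, with overlapping plates for both.

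The GFP sorts differed in how many GABAergic nuclei they held. GABAergic neuron-like nuclei were 75.8% of somatosensory cortex (68.2 to 82.5%), 56% of M2 cortex (48.1 to 63.6%), 88 of 440 in hippocampus (16.4 to 24%) and 16.9% of striatum (12 of 71, 9.05 to 27.7%). In hippocampus 35.5% were glutamatergic neuron-like (31 to 40.1%), and 44 of 440 were ependymal cell-like and 5.68% astrocyte-like. Neuron-like nuclei without a transmitter call met neither the GABAergic nor the glutamatergic threshold, both set after the markers were seen. They were 10.2% of hippocampus, 33.9% of M2 cortex, 17.4% of somatosensory cortex and 31% of striatum. Unnamed clusters held 18.6%, 8.33%, 6.04% and 7.04% of the same regions. In nuclei without a transmitter call, the vesicular glutamate transporter Slc17a7 was found in 57%, Gad1 in 28.5%, Gad2 in 48.3% and Pvalb in 7.28%. These shares were 84.9%, 29.6%, 22.9% and 3.35% in the glutamatergic class and 14.3%, 92%, 82.2% and 69.4% in the GABAergic class. All include the hippocampal nuclei without a sort label. The class without a call thus lay near the glutamatergic class for Gad1 and Pvalb, and between both for Slc17a7 and Gad2. With a coarser clustering resolution of 0.5 the hippocampal glutamatergic share was 20.7%.

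Each region's GABAergic nuclei were compared with those of the other GFP-sorted regions, which asks what separates Pvalb interneurons by area. Hippocampal nuclei had higher means of the AMPA receptor auxiliary gene Shisa6, with a log2 ratio of 4.07, of the semaphorin receptors Nrp2 and Nrp1 at 3.03 and 2.87, and of the matrix link protein Hapln1 at 2.55. M2 nuclei had higher Rbp4, a retinol carrier, at 2.92, and Ptgs1, a prostaglandin synthase, at 2.12. In somatosensory cortex the synaptotagmin Syt15 stood at 2.84 and the decay factor Upf1 at 2.59, while the neuronal phosphoprotein gene Arpp21 stood at -3.11. The 12 striatal nuclei had higher means of the receptor kinase Kit, at 5.29, and of Nkx2-1, at 4.98, a factor kept by striatal but not cortical interneurons. Tac1 and Cck were listed at 0 in these striatal nuclei. Hippocampal nuclei lay mostly in 1 GABAergic cluster (80 of 88) and somatosensory nuclei in another (all but 1), and each region had its own plates, so region, cluster and plate cannot be separated. When differences of mean log2 values were used, 3 of 24 genes named by the rule for hippocampus stayed named, 4 of 17 for M2 cortex, 3 of 24 for somatosensory cortex and 6 of 24 for striatum.

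Within the TRN, Spp1 and Ecel1 marked opposite ends of a range of GABAergic nuclei, which addresses the molecular gradient of the series title. Spp1 (ENSMUSG00000029304.14, chromosome 5, 104435118 to 104441050) encodes the secreted glycoprotein osteopontin and Ecel1 (ENSMUSG00000026247.13, chromosome 1, 87147655 to 87156521) a neuronal metalloprotease. Their expression was negatively correlated across nuclei on each of 13 plates, with a median Spearman rho of -0.458 (-0.621 to -0.299, SD 0.0934 over plates). The median was -0.502 on 5 unselected plates and -0.389 on 8 NeuN plates. On the unselected plates no nucleus held both transcripts, and on NeuN plates 2.74 to 10.3% did. Spp1 was found in 37.5% of TRN GABAergic nuclei and 2.70% of TRN glutamatergic nuclei, and Ecel1 in 37.1% and 0.541%, at median detected genes of 4761 and 4966. Random gene pairs matched on mean TPM reached this rho in 0.04% of 10000 draws, but their members were found in far more nuclei than Spp1 and Ecel1. The pair was chosen because these genes are known to mark the ends of the TRN gradient. Its rank among random pairs is therefore no independent support for a gradient.

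**Figure D3:**
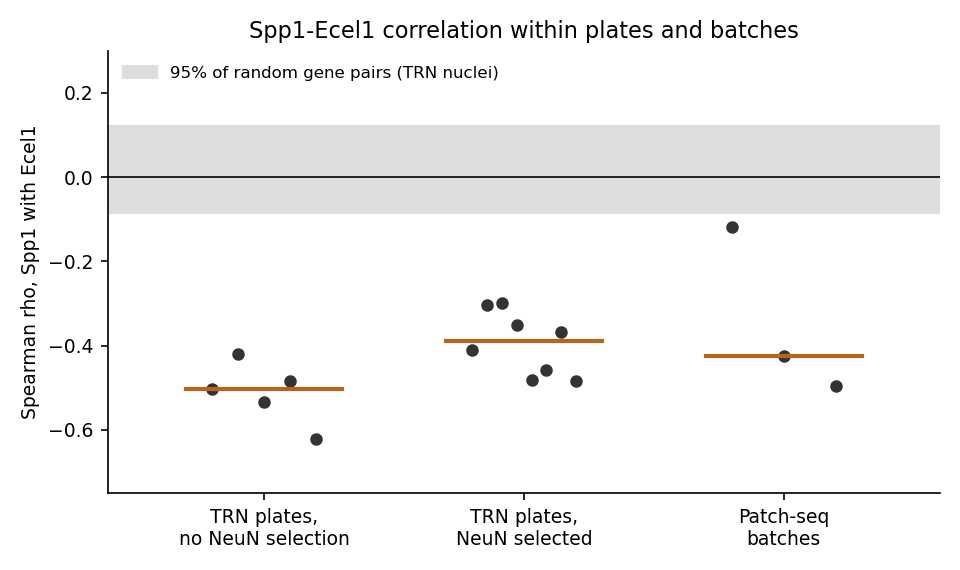
Spearman rho of Spp1 with Ecel1 (vertical axis) across nuclei of each TRN plate and libraries of each Patch-seq batch (points), with group medians (lines). The band (-0.0846 to 0.122) is the 95% range, over random gene pairs matched on the share of nuclei, of the median rho over the TRN plates. It applies to the median over the 13 plates, -0.458, and not to single plates or batches. The plates lie between -0.621 and -0.299.

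Genes of excitability lay at both ends when nuclei were ordered by Spp1 minus Ecel1: 4 of 7 Kv1 and Kv3 channels, 4 of 7 T-type, SK and HCN channels and 5 of 8 sodium channel genes had positive correlations. The median rhos of these lists leaned to the Spp1 end, at 0.379, 0.217 and 0.168. They stood at the 100, 100 and 99.9 percentiles of random lists matched on expression. High percentiles were not particular to excitability. Perineuronal net genes stood at 100, immediate early genes at 98.9 and nuclear-retained RNAs at 96.2, while forebrain patterning factors stood at 50.5 and ribosomal protein genes at 0.89. The cluster with most Spp1 had a median of 5449 detected genes, against 4851 in that with most Ecel1. List percentiles were not computed with detected genes partialled out. GABA-A subunits leaned to the Ecel1 end, with a median of -0.116 at the 0 percentile and 4 of 9 positive. At the Spp1 end lay the sodium channel subunit Scn4b, with a mean within-plate rho of 0.654, the calmodulin-binding gene Pcp4l1 at 0.558, the fast synaptotagmin Syt2 at 0.547 and the neurofilaments Nefh and Nefm at 0.540 and 0.504. The potassium channels Kcna1 and Kcnc1 (0.511 and 0.460), which support rapid firing, the T-type channel Cacna1h (0.473) and Pvalb (0.307) lay on the same side. Genes of perineuronal nets, the matrix around fast-spiking neurons, had a median rho of 0.271, and all 6 that could be tested were positive. At the Ecel1 end lay the RNA-binding gene Celf4 at -0.520, the reticulon Rtn1 at -0.507, the membrane glycoprotein Gpm6a at -0.499, the T-type channel Cacna1g at -0.378, the potassium channel Kcnc4 at -0.316 and Sst at -0.258. Across 8691 genes, which are not independent replicates, the correlations on unselected and on NeuN plates had a Pearson r of 0.618. That r was 0.385 at clustering resolutions 0.5 and 2, each of which left 1 unselected plate with at least 20 GABAergic nuclei, and 0.397 among nuclei with either gene.

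The 95 Patch-seq libraries, which sample cytoplasm, were compared with GABAergic NeuN-selected nuclei to ask how recorded TRN neurons relate to sorted nuclei. Both held the TRN genes: Pvalb had a log2 ratio of 0.20 and Six3 -0.44. Within batches the rho of Spp1 with Ecel1 was -0.496 over 34 libraries, -0.424 over only 7 and -0.118 over 54, the last closer to 0 than the SD between batches of 0.201. The axis correlations of 8655 genes in nuclei correlated across genes with those of the batches. The r was 0.516 for the batch of 34 libraries, 0.138 for that of 7 and 0.353 for that of 54. Patch-seq libraries also held transcripts of other cells. The complement gene C1qb, made in brain by microglia (chromosome 4, 136880129 to 136886187, mm10), averaged 261.6 TPM in Patch-seq and 0.282 TPM in nuclei, a log2 ratio of 7.68, and all 9 microglial markers were higher, with a median of 5.23. At least 2 of C1qa, C1qb and Ctss were found in 38 of 95 libraries and in 2 of the nuclei (0.342%). The microglial adaptor Tyrobp was found in 35.8% of libraries and listed at 0 in the nuclei. The haemoglobin genes Beta-s and Hba-a1 of red cells had ratios of 9.50 and 7.53, and the 8 astrocyte markers a median of 2.30. As differences of mean log2 values the microglial and astrocyte medians were 2.23 and 0.82.

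**Figure D4:**
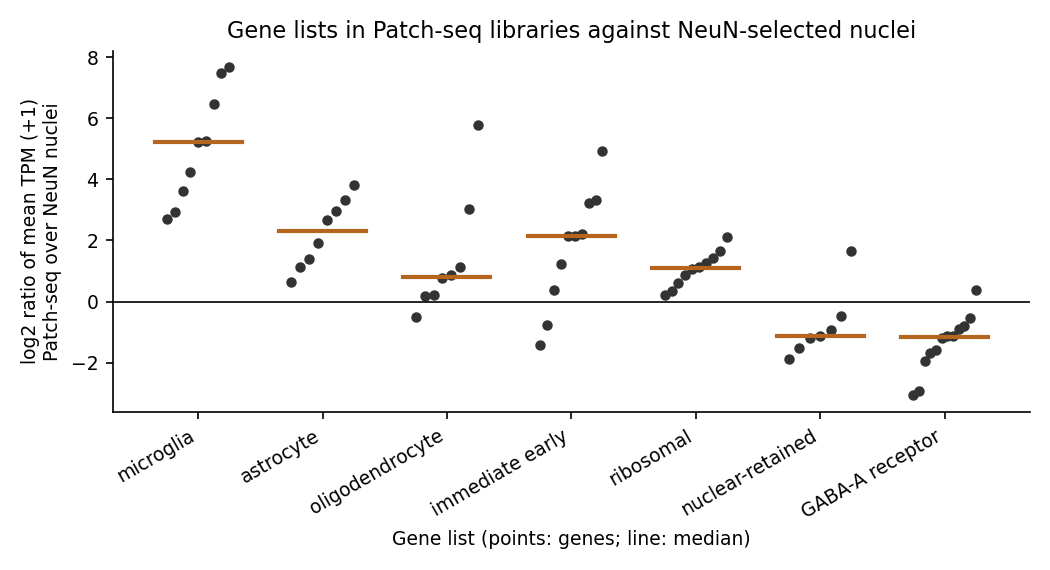
Log2 ratio of mean TPM plus 1 (vertical axis), Patch-seq libraries over NeuN-selected GABAergic nuclei, for the genes (points) and medians (lines) of 7 gene lists. The microglial median is 5.23 and the nuclear-retained RNA median -1.12.

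Patch-seq libraries also differed in RNA expected of cytoplasm and of recent activity. The nuclear RNA Malat1 was lower in Patch-seq, at -1.89, and 6 of 7 nuclear-retained RNAs were lower, with a median of -1.12. All 10 ribosomal protein genes were higher, with a median of 1.09, including Rplp1 at 2.12. The immediate early genes Fosb, Junb and Fos, induced by stimulation, had ratios of 4.92, 3.34 and 2.23, and 8 of 10 such genes were higher, while Arc was lower at -0.77. GABA-A receptor subunits had a median of -1.17, with Gabrb1 at -2.94. As differences of mean log2 values the medians were -1.83 for nuclear-retained RNAs, 2.41 for ribosomal protein genes and -0.43 for GABA-A subunits, and the first was -0.71 on the deposited scaling. The median ratio over all genes found in 20% of either group was -0.62, against which the lists should be read, and the tables were deposited separately with 6654 and 4947.5 median detected genes. Lars2, at 7.64, is left uncertain because reads from abundant ribosomal RNA can be assigned to it. Of the 24 genes named by the rule in Patch-seq, 4 stayed named with differences of mean log2 values.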

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

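These values stood apart from the samples around them or came from samples outside the comparisons, and none was tested against an explanation. On the adjacent plate ThrP26, 96.3% of neuron-like nuclei were glutamatergic (26 of 27), far from the other adjacent plates, where 1.54% were. Of 12 groups of plates tested for a plate far from the others, this was the 1 found; chance flags about 1 in 20 groups. The names of the other 3 adjacent plates begin with GPE or gpe, and the group covers both thalamus and globus pallidus, so these plates need not be replicates of 1 tissue. Y-linked transcripts were found in 18.9% of Patch-seq libraries (18 of 95, 11.6 to 28.3%), a signal no comparison used, against 1.20% of GABAergic NeuN-selected nuclei. Xist, the RNA of the inactive X chromosome, was found in 76 of the 95 libraries, 18 held a Y-linked gene and 13 held both. Of those 13, 10 came from the batch of 34, where no library held 2 or more Y-linked genes. All 7 libraries with 2 or more came from the batch of 54. Over the groups of nuclei Xist was found in 97.1 to 100% and a Y-linked gene in at most 2.82%, so sex may differ between nuclei and some Patch-seq cells. Xist is also on the list of nuclear-retained RNAs. Among 43 hippocampal nuclei without a sort label, which entered no comparison, 16.3% were GABAergic neuron-like (7 of 43, 6.81 to 30.7%) and 51.2% glutamatergic neuron-like (22 of 43, 35.5 to 66.7%).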

How the results depend on the processing

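The alternatives with the deposited scaling, without the Pvalb-low cluster, over 20 clustering starts and with random pairs matched on the share of nuclei, and every alternative for the striatal and microglial medians and the hippocampal shares, were chosen after seeing the data; all others were fixed before the data were examined. Of the values that answer a comparison, 77.6% moved by less than their spread, 37 moved by more and 1 changed sign. Named genes outside the Spp1 minus Ecel1 axis stayed within their spread in 78.6% of values, moved in 19.4% and reversed in 15 values, all in the adjacent comparison. For the axis genes 99.1% stayed within it and none reversed. A named gene counted as reversed only where its plates lay apart in the main setting. An axis gene counted only where the size of its mean rho exceeded its SD over plates. Other sign changes were counted by size alone, as within the spread or moved. Unless stated, the cause was not tested.

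By these rules only the striatal result and genes named beside it reversed. Without the Pvalb-low cluster, which held 26 of the 65 adjacent nuclei, the striatal median was -0.0495, 2 of 24 genes stayed named, and Bcl11a was -1.07, Arpp21 -1.14, Drd1a -1.37, Drd2 -0.10, Tac1 -0.0928, Pdyn -0.83, Foxp1 -0.44 and Calb1 -1.12; the loss of those nuclei is built into this alternative. At resolution 2, which moved 18 of them to another class, the median was 1.14, 1 of 24 genes stayed named, and Arpp21 was -0.27, Kcna4 -1.76, Drd2 -0.90, Tac1 -1.15, Foxp1 -0.19, Gabrd -0.78 and Calb1 -2.49.

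Clustering moved other values. Resolution 0.5 gave 96.8% neuron-like NeuN-selected nuclei and 20.7% glutamatergic hippocampal nuclei. The correlation across genes between unselected and NeuN plates was 0.385 at resolutions 0.5 and 2, which left 1 unselected plate each; in the main setting single unselected plates gave 0.312 to 0.417, so fewer plates account for it. It was 0.547 with detected genes partialled out and 0.397 in nuclei with Spp1 or Ecel1, where rho was -0.776. Over the 20 starts the NeuN-selected neuron-like share reached 98.7%, the striatal median fell to 1.03 and the hippocampal glutamatergic share to 19.3%. At resolution 2 M2 cortex kept 11 of 17 named genes.

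Without the 10% of nuclei with the fewest detected genes, unselected nuclei were 49.9% neuron-like and the microglial median was 4.83. A pseudocount of 10 TPM gave medians of -2.22 (MGE), 3.33 (striatal) and 2.89 (microglial), and kept 15 of 24 striatal named genes. Differences of mean log2 values gave -2.44, 2.02 and 2.23, and kept 0 of 1 named gene by sort, 8 of 24 for adjacent tissue, 11 of 24 for TRN against GFP sorts, 3 of 24 for hippocampus, 4 of 17 for M2, 3 of 24 for somatosensory cortex, 6 of 24 for striatum and 4 of 24 for Patch-seq. The deposited scaling gave a striatal median of 4.64.

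Leaving out 1 plate or batch at a time gave neuron-like shares of 39.4 to 42.9% (unselected), 94.4 to 95.4% (NeuN) and 34.2 to 45.1% (adjacent), and glutamatergic shares of 1.54 to 42.9% (adjacent, lowest without plate ThrP26) and 18.1 to 19% (TRN). Medians ranged from -4.26 to -3.87 (MGE), 0.57 to 0.89 (T-type, SK and HCN), 4.78 to 5.38 (striatal) and 5.14 to 5.26 (microglial). The Spp1-Ecel1 correlation ranged from -0.469 to -0.439 in the TRN and from -0.460 to -0.271 in Patch-seq, the correlation across genes from 0.560 to 0.614, and the hippocampal shares from 18.5 to 22.4% (GABAergic) and 32.6 to 38.3% (glutamatergic).

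No paired analysis was possible because each sample is 1 nucleus or cell whose number only orders samples within its group, and no result comes from a test. The alternatives for the mitochondrially encoded share were not run, since none of its genes was measured in the tables used here. Read depth is unknown: a gene listed at 0 may lie below what a library could detect, and without the nuclei with the fewest detected genes the unselected neuron-like share rose to 49.9%.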

Other observations

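Gene groups not described above had these values in TRN against GFP-sorted GABAergic nuclei. Genes of GABA synthesis, release and uptake had a median log2 ratio of 1.43 (0.95 with a pseudocount of 10 TPM), with 5 of 6 higher in the TRN. Of the sodium channel genes 7 of 8 had higher means, with a median of 0.47 (0.16 to 1.02 over the scalings tried) and Scn3a at 2.86. Ionotropic glutamate receptors had a median of -0.63 (-0.96 to -0.33 over the scalings tried), with 4 of 15 higher, and interneuron neuropeptides -1.23, with 3 of 9 higher, which came to -0.07 as a difference of mean log2 values. The transcription factor Zfhx3 stood at 2.93 and the orphan receptor Gpr83 at -4.08. Along the TRN axis the metabotropic glutamate receptor Grm3 (mean within-plate rho 0.438), the GABA-synthesising enzyme Gad1 (0.409), the T-type channel Cacna1i (0.334) and the perineuronal net genes Hapln4, Bcan and Acan (0.431, 0.389 and 0.327) lay at the Spp1 end. The sodium pump subunit Atp1b2 (-0.489), the vesicle gene Nsg2 (-0.452), the sodium channel subunit Scn3b (-0.382) and the GABA-A subunit Gabrb1 (-0.372) lay at the Ecel1 end.

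Regions and Patch-seq held further differences. Among GFP-sorted GABAergic nuclei the collagen Col25a1 and the calcium sensor Hpca stood at 2.96 and 2.88 in hippocampus against the other regions, the lipase Lpl at 1.85 in M2 cortex, and the chaperone Hspa5 at -1.82 and the immunity-related GTPase Irgm1 at -2.70 in somatosensory cortex. In Patch-seq against NeuN-selected GABAergic nuclei the microglial receptors Csf1r and Cx3cr1 stood at 5.25 and 5.23, the myelin gene Mbp at 5.78 and the astrocyte genes Gja1 and Gfap at 3.83 and 3.33. Metabotropic glutamate receptors had a median of -1.34 there, with 1 of 7 higher, but -0.10 as a difference of mean log2 values.

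Of the tests that follow, these were chosen only after the result was seen: the one without the Pvalb-low cluster, all those on hippocampal nuclei, and the one that sets microglial against oligodendrocyte markers. Within TRN plates Spp1 and Ecel1 were negatively related, with a median rho of -0.458. The tables argue against detected genes as the whole cause, since with their number partialled out the median rho was -0.394 (plates -0.552 to -0.207), and against a separate Pvalb-low cluster, without which it was -0.485 (-0.603 to -0.288). They also argue against 1 abundant transcript lowering all others, because the 1000 most abundant genes had a median rho with Spp1 of 0.0306. No draw of 10000 random pairs matched on the share of nuclei, an alternative chosen after seeing the data, was as low, and the lowest was -0.192. Since the pair was chosen as known ends of the gradient, that rank is no independent support. A graded or two-ended difference between TRN neurons may account for it, as a hypothesis found and tested on the same nuclei, and where each nucleus lay in the TRN was not analysed here.

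In the hippocampal GFP sort 35.5% of nuclei were glutamatergic neuron-like. Free RNA of glutamatergic neurons in GABAergic nuclei was examined with the MGE genes. They were found in glutamatergic nuclei at a median of 10.3% of their share in GABAergic nuclei, with separate intervals for 7 of 7 genes. The clusters were formed from the expression of these same nuclei, so such a separation is partly built in and the test cannot decide. It replaced one on Gad1 and Gad2, which also name the classes. A pattern of 1 of the 2 sets of plates was argued against by the lowest share on any plate, 17.5%, although the sets differed (39.5 to 48.7% on 4 plates, 17.5 to 30.4% on 3). A candidate explanation that stays open is that the sort let nuclei through without Pvalb transcripts: Pvalb was found in 3.21% of glutamatergic nuclei (1.05 to 7.32%), 71.6% of GABAergic and 14.5% of ependymal cell-like and astrocyte-like nuclei together, at median detected genes of 4104.5, 5390.5 and 3191. Earlier Pvalb expression, lost by the time of sorting, may give the same values, and the design gave no group to test it.

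In Patch-seq libraries microglial markers had a median log2 ratio of 5.23 to nuclei. Free tissue RNA in the proportions of its cell types was argued against, since that median exceeded the oligodendrocyte median (0.82) by 4.41, though the gap narrowed to 2.89 against 0.69 with a pseudocount of 10 TPM and to 2.23 against 1.08 as differences of mean log2 values. Deeper libraries were argued against too: of 31 libraries with no more detected genes than the median nucleus, 22.6% (9.59 to 41.1%) held at least 2 of C1qa, C1qb and Ctss. Microglial RNA picked up by some pipettes is a candidate explanation, because the 38 libraries with at least 2 of those genes had a median of 3 of 6 other microglial markers against 1 in the 39 with none, a difference of 2 that lay exactly at the limit fixed in advance. No biological explanation was tested, since Patch-seq forms a single group.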
